A study of Mus musculus with 12 samples.

How the data were processed

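Per the submitters' processing notes, reads were aligned with STAR and counted per gene with featureCounts, and the versions, the annotation and the strand setting are not given in the sources used here. The notes name the genome builds mm9 and mm10 without saying which step used which, so no coordinates are printed. Per the labels, total RNA was isolated with an RNeasy kit and polyA RNA was sequenced. The values used were the deposited counts, whole numbers of reads per gene symbol with no normalization, for 23762 genes in 12 libraries. No gene symbol was duplicated, and 5850 genes were at 0 in every library. Other assays named in the series title were not used here.

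Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes with low counts were removed with filterByExpr of edgeR, library sizes were scaled with TMM factors, and groups were compared with the robust quasi-likelihood F test of edgeR (glmQLFit and glmQLFTest). Genes passed at a Benjamini-Hochberg adjusted p under 0.05. Levels are given as CPM, the count of a gene relative to the library total scaled with its TMM factor, as mean ± SD over the libraries of a group, computed within the libraries of each fit. The standard error (SE) of a log2 fold change is its size divided by the square root of its F value. Values in brackets after a gene name with no unit, and values after the words changed by, are log2 fold changes with their SE where given. Each adjusted p of a gene is from edgeR unless another tool is named.

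The 6 follicular libraries were fitted alone for the comparison of deleted with control cells. The 6 germinal centre libraries were fitted together for the 3 comparisons between sorted fractions, so that the fractions shared 1 estimate of the spread. For germinal centre against follicular cells, the 6 germinal centre libraries and the 3 deleted follicular libraries were fitted together, and the mean of the 3 fractions was compared with the follicular mean. No germinal centre libraries from control animals were among the samples, so the fractions were compared as sorted fractions and not as genotypes.

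The tests, the groups, 34 gene lists and the rule for the genes to name were fixed before the data were examined. The rule named the 12 genes with the largest rise and the 12 with the largest fall among genes past the threshold, with a mean log2 CPM of at least 3 and no overlap between the libraries of the groups compared. It left out antigen receptor segments, numbered gene models, clone names, ribosomal protein pseudogenes and the markers used for sorting. It added up to 4 members of each list with the smallest p-values, Brwd1 and its relatives Brwd3 and Phip, the sort markers and sex-linked genes. Of 440 list symbols 419 were found in the table, 6 of them under an older symbol. The genes of the mitochondrial genome, Igkc, the Iglc genes, Trac and Hbb-bt had no row, so the mitochondrial list was not tested.

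Lists with at least 5 tested genes were tested with camera of edgeR at a preset inter-gene correlation of 0.01, which compares a list with all other genes. Camera was repeated with a correlation estimated from each list, and the lists were also tested with fry, which asks whether the members of a list move one way on balance. With an estimated correlation camera also has few degrees of freedom, because the libraries are few. Its unadjusted p rose even where the estimate lay below 0.01, as for myeloid markers in LZ against DZp (-0.0712, p from 1.04e-07 to 0.0109). A call lost in that setting therefore does not show that correlated members made it. Where the estimate lay far above 0.01, as for immediate early genes in follicular cells (0.625), the p from the preset may be too small. Benjamini-Hochberg adjustment for lists ran over the lists of a comparison. Some lists share members, so their results are not independent. The light zone list shares Nfkbia, Nfkb1, Nfkb2, Rel, Traf1, Icam1, Bcl2a1b and Cd40 with the NF-kB targets. It shares Egr1, Egr2, Egr3 and Nr4a1 with the immediate early genes. Aicda, Gcsam and Mybl1 are in the dark zone and germinal centre identity lists, and Cd38, Klf2, S1pr1 and Bcl2 in the follicular and memory lists. Cxcr4 and Cd83 were left out of lists between fractions, and Fas, Cr2, Fcer2a and Cd93 out of lists between germinal centre and follicular cells, because they had been used in the sorts.

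The alternatives tried were size factors of DESeq2, upper-quartile factors, leaving out immunoglobulin genes, no filter, a mean count of at least 50, DESeq2 itself, limma-voom with and without sample quality weights, a test against a change of 1.5-fold (glmTreat), a threshold of 0.01, leaving out each library in turn, the replicate number as a block, and other sets of libraries in the fit. Added after the data had been seen were the sex of the follicular libraries as a covariate, leaving out the ribosomal RNA repeat Rn45s, and leaving out genes that share at least 10% of their 31-base words with another annotated gene. Shared words were counted in GENCODE mouse transcripts, to which 23211 genes (97.7%) were matched.

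The test was run on simulated counts with the depth and spread of each comparison, with 50 genes changed at each of 1.3, 1.5, 2 and 4-fold. The changed genes were drawn only from genes above a minimum mean CPM, so the recovery does not cover low genes. Only 200 genes changed, unlike in the germinal centre data, and the fractions shared 1 spread, which the data need not do. For deleted against control follicular cells 17, 42, 48 and 50 of them were called, with 11 false among 168 calls. For LZ against DZp 25, 50, 50 and 50 were called, with 14 false among 189, and for DZd against DZp 33, 44, 50 and 50, with 11 false among 188. For LZ against DZd 25, 47, 50 and 49 were called, with 15 false among 186, and for germinal centre against follicular cells 38, 48, 50 and 50, with 7 false among 193. Camera found the 1 simulated list with a 1.5-fold rise in each comparison. Its members were drawn independently and all rose, so lists with correlated members were not tested.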

Results

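Gene expression was measured by polyA RNA sequencing in 12 libraries of sorted mouse splenic B cells carrying a conditional allele of Brwd1, which encodes a chromatin reader with bromodomains and WD repeats. Follicular B cells, sorted as B220+ CD93+ CD21+ CD23+ per the labels, came from Cd23-Cre Brwd1fl/fl mice as tdTomato+ cells (deleted, 3 libraries) and from Brwd1fl/fl mice without Cre (control, 3 libraries). Germinal centre B cells, sorted as B220+ GL7+ CD95+ tdTomato+, came from Aicda-Cre Brwd1fl/fl mice on day 14 after immunization with sheep red blood cells and a boost on day 5. They were split into LZ (light zone, CXCR4- CD83+), DZp (CXCR4+ CD83+) and DZd (CXCR4+ CD83-) cells, with 2 libraries each. The titles call the DZp libraries GZ and the DZd libraries DZ, and the gates and names used are those of the cell type labels of the same samples. Cd93 transcript was low in follicular libraries, at 203 to 368 counts, so the CD93+ gate rests on the labels alone. Total counts were 26.0, 24.2 and 21.9 M in the deleted and 26.0, 21.2 and 19.4 M in the control follicular libraries. They were 46.4 and 47.1 M in LZ, 42.4 and 43.4 M in DZp, and 40.5 and 39.0 M in DZd. The labels do not say whether replicates came from separate animals, so p-values measure the spread between these samples. Each of the germinal centre libraries held counts of both Xist and Y-linked genes, as pools of animals of both sexes would. If they were pools, or parts of the same pool, the spread between the libraries of a fraction does not measure the spread between animals. Among follicular libraries, deleted replicate 1 and control replicates 1 and 2 held Xist and no Y-linked counts, and the other three held Y-linked counts with at most 3 counts of Xist.

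The comparison of deleted with control follicular B cells asks which transcripts differ when Brwd1 is removed before antigen encounter. Deleted cells also carried Cre and were sorted as tdTomato+, while controls had no Cre. Effects of Brwd1 loss cannot be told apart from those of Cre, the reporter or the sort. Brwd1 itself fell in deleted cells, to 288 ± 12.4 CPM from 428 ± 16.6 CPM in controls (SD, n = 3 each), a log2 fold change of -0.57 ± 0.06 (SE) with an adjusted p of 0.00902. Its transcript stood at 67.2% of the control mean, from 64.5% to 70.3% in single deleted libraries, and counts per gene do not separate the deleted exons from the rest. Trappc5, a subunit of a vesicle-tethering complex, rose from 65.0 ± 4.90 to 99.0 ± 5.58 CPM (log2 fold change 0.61 ± 0.07, adjusted p = 0.0152). Bcl10, the adaptor that links the antigen receptor to NF-kB, rose from 106 ± 4.53 to 142 ± 5.69 CPM (log2 fold change 0.43 ± 0.06, adjusted p = 0.0477). The relatives of Brwd1 did not pass, with log2 fold changes of -0.24 ± 0.12 for Brwd3 (adjusted p = 0.591) and -0.02 ± 0.06 for Phip (adjusted p = 0.938). The follicular sort markers Cr2, at 1621 ± 180 and 1497 ± 32.2 CPM, and Fcer2a, at 1485 ± 45.4 and 1342 ± 178 CPM in deleted and control cells, did not pass either.

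**Figure D1:**
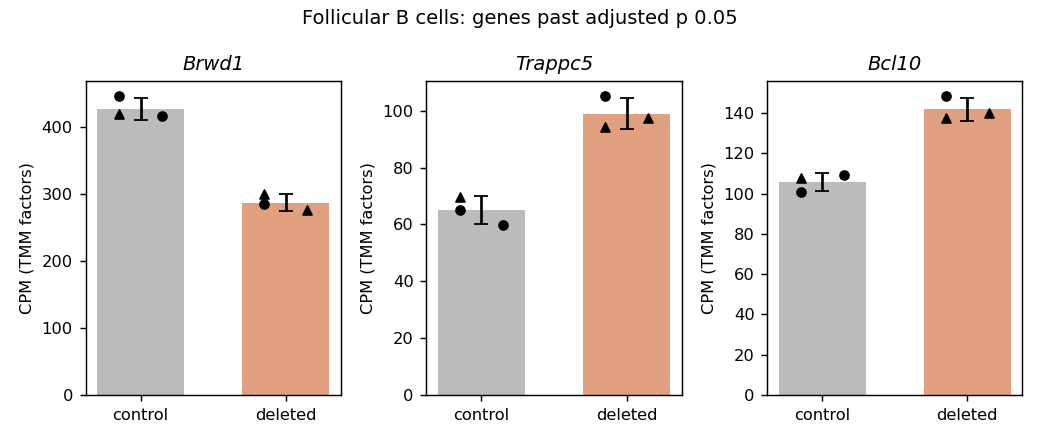
Level of the 3 genes past adjusted p 0.05 in follicular B cells, in CPM with TMM factors. Bars are group means, error bars SD (n = 3), and points single libraries, circles for libraries with Xist counts and triangles for libraries with Y-linked counts. In each panel the deleted libraries lie apart from the control libraries.

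Immediate early genes, which are switched on within minutes of receptor or stress signals, were higher as a group in deleted follicular cells. That call rests on the preset correlation of camera and did not hold with an estimated correlation or with fry. All 19 measured members had positive log2 fold changes, with a median of 0.64 (camera adjusted p = 1.36e-11, adjusted p = 0.456 with an estimated correlation of 0.625, and fry adjusted p = 0.309). In edgeR none of the 19 passed over all genes tested, and 1, Ier5, passed when adjusted over the list alone. Over all genes DESeq2 called Ier5 (adjusted p = 9.11e-06) and Jun (0.000591), edgeR with sex as a covariate Ier2 (0.0252) and Ier5 (0.032), and edgeR with the replicate block Dusp2 (0.014). Jun, a subunit of AP-1, stood at 341 ± 193 CPM in deleted and 44.2 ± 12.1 CPM in control cells (adjusted p = 0.441), and Ier5 at 444 ± 93.7 and 282 ± 11.3 CPM (adjusted p = 0.366). The phosphatase gene Dusp1 stood at 89.1 ± 53.8 and 19.9 ± 6.98 CPM (adjusted p = 0.520). The list medians of single libraries were 1.06, 0.60 and 0.11 in deleted and 0.31, 0.01 and -0.21 in control libraries, so they overlapped. The inducible heat shock genes Hspa1a at 396 ± 273 and 29.96 ± 4.03 CPM and Hspa1b at 994 ± 559 and 139 ± 13.6 CPM passed in edgeR over the heat shock list alone but not over all genes (adjusted p = 0.441 and 0.437). DESeq2 called both over all genes (7.79e-05 and 0.000293). That list had a median of -0.10, a mean of 0.54 and a camera adjusted p of 0.0578 towards higher values.

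The light zone list, which holds genes induced by CD40 and receptor signals, had a median log2 fold change of 0.12 over 23 genes (camera adjusted p = 0.000798, and adjusted p = 0.327 with an estimated correlation). Among its members Myc stood at 112 ± 20.1 and 75.2 ± 12.6 CPM (adjusted p = 0.476) and Nfkbia, an NF-kB inhibitor, at 275 ± 19.9 and 243 ± 10.2 CPM (adjusted p = 0.468). NF-kB targets, several of which are also in the light zone list, had a median of 0.10 over 14 genes (camera adjusted p = 0.0233, and adjusted p = 0.327 with an estimated correlation). The NF-kB call was lost without deleted replicate 1 (0.132), deleted replicate 3 (0.0704) or control replicate 1 (0.0586). In edgeR no member of these lists passed over all genes or adjusted over the list alone. Over all genes Myc passed with DESeq2 (0.00295), with the replicate block (0.014) and with sex as a covariate (0.032). Ribosomal protein genes had a shift of similar size in the same libraries, with a median of 0.14 over 79 genes. DESeq2 called Rpl36 (0.40), Rpl35 (0.35) and Rps21 (0.30) higher and the nuclear RNAs Malat1 (-0.40) and Neat1 (-0.44) lower.

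Survival genes were mixed. The BCL2 family had a median of 0.10 over 12 genes (camera adjusted p = 0.0458, and adjusted p = 0.456 with an estimated correlation), with 1 gene higher and 1 lower when adjusted over the list alone and none over all genes in edgeR. The survival factor Bcl2 stood at 229 ± 10.8 and 187 ± 11.6 CPM (adjusted p = 0.278) and the death-promoting Bcl2l11 at 55.8 ± 3.31 and 67.2 ± 6.61 CPM (adjusted p = 0.414). Over all genes Bcl2 passed with DESeq2 (0.0138), without a filter (0.0469) and with all 12 libraries in 1 fit (0.0251). That list call was lost without deleted replicates 1 (0.189), 2 (0.0668) or 3 (0.0684) and control replicates 1 (0.0523) or 2 (0.237), and with sex as a covariate (0.0794). The p53 targets had a median of 0.14 over 10 genes (camera adjusted p = 0.0424, and adjusted p = 0.553 with an estimated correlation), with 1 gene, the cyclin gene Ccng1, higher when adjusted over the list alone. The p53 call was lost without deleted replicate 1 (0.189) or control replicate 2 (0.162), with sex as a covariate (0.112) and with the replicate block (0.0504).

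Genes for the immunoglobulin constant regions were lower as a group, with a median of -0.22 over 7 genes (camera adjusted p = 0.00255, adjusted p = 0.456 with an estimated correlation of 0.379, and fry adjusted p = 0.309). Ighd, the constant region of surface IgD, stood at 2107 ± 132 CPM in deleted and 2447 ± 131 CPM in control cells (adjusted p = 0.441), and the call was lost without deleted replicate 3 (0.132). Migration receptors had a median of -0.11 over 12 genes (camera adjusted p = 0.0210, and adjusted p = 0.327 with an estimated correlation). Among them S1pr2 stood at 1.27 ± 0.453 and 2.45 ± 0.361 CPM (adjusted p = 0.441), and the call was lost without deleted replicate 3 (0.0977) or control replicate 2 (0.0550). The BRWD and BET family list, which contains Brwd1, was lower (median -0.06, camera adjusted p = 0.0106, adjusted p = 0.327 with an estimated correlation, and fry adjusted p = 0.112), and lost its call without deleted replicate 3 (0.0704). Brwd1 was its only member past the threshold over all genes, so part of the call follows from the deletion. The list was not tested without Brwd1. Oxidative phosphorylation genes had a median of 0.07 over 24 genes (camera adjusted p = 0.0338, and adjusted p = 0.473 with an estimated correlation). That call was lost without deleted replicates 1 (0.132) or 3 (0.143) and control replicates 1 (0.125) or 3 (0.0652). The G2/M list of mitotic genes had a median of 0.15 over 21 genes (camera adjusted p = 0.0263, adjusted p = 0.703 with an estimated correlation of 0.566, and fry adjusted p = 0.715). It was lost without deleted replicate 2 (0.805), turned direction without control replicate 2 (0.731) and was lost with sex as a covariate (0.386).

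Markers of myeloid cells were also higher as a group in the deleted libraries, with a median of 0.43 over 12 genes (camera adjusted p = 0.000405, adjusted p = 0.473 with an estimated correlation of 0.426, and fry adjusted p = 0.349). Adjusted over the list alone, 2 genes passed. The complement gene C1qa stood at 3.52 ± 0.843 and 1.43 ± 0.588 CPM (adjusted p = 0.366) and the macrophage receptor Csf1r at 6.17 ± 1.27 and 3.16 ± 1.87 CPM (adjusted p = 0.519), and DESeq2 called C1qa over all genes (0.0498). Outside the list DESeq2 also called Vcam1 (2.98e-05) and Trf (0.00508) higher, and neither passed in the main edgeR fit. The myeloid call was lost without deleted replicate 3 (0.179) or control replicate 2 (0.0924), and the list medians of single libraries were 0.18, 0.35 and 0.94 in deleted and 0.45, -0.39 and -0.01 in control cells. Markers of T cells, with a median of -0.54 over 10 genes (camera adjusted p = 0.148), and of NK cells, with -0.38 over 7 genes (0.171), pointed the other way, as the migration receptors did, and did not pass. Germinal centre identity genes had a median of -0.21 (camera adjusted p = 0.0578) and early B lineage genes of -0.17 (0.0625). MHC class II genes had a median of -0.01 (0.741), B cell receptor signalling genes of -0.04 (0.148) and G1/S genes of 0.03 (0.833), and none of these lists passed. Follicular and naive genes had a median of -0.05, a mean of 0.01 and 1 gene, Bcl2, higher when adjusted over the list alone (0.903).

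Of 11511 genes tested, 3 passed in edgeR, 2 higher and 1 lower in deleted cells. At an unadjusted p under 0.05 there were 1045 genes (9.1%), 493 higher and 552 lower, and the groups did not overlap in 1768 genes (15.4%, where chance gives 10%). The count was 7, 13 and 34 without deleted replicates 1, 2 and 3, and 0, 0 and 3 without control replicates 1, 2 and 3. The adjusted p of Brwd1 ran from 9.78e-15 with DESeq2 to 0.0760 without control replicate 2, and it also missed the threshold without control replicate 1 (0.0602). In the glmTreat test against 1.5-fold, left out of these ranges, each of the 3 genes had an adjusted p of 1. Trappc5 ran from 4.84e-09 with DESeq2 to 0.119 without control replicate 2, with 0.0685 without control replicate 1. Bcl10 ran from 9.21e-06 with DESeq2 to 0.200 without control replicate 3, and it missed without deleted replicate 1 (0.142), control replicate 1 (0.161) or control replicate 2 (0.146), with limma-voom (0.0535) and with the replicate block (0.0749). The first principal component, with 35.4% of the variance, parted the libraries by sex and not by genotype. Sex was unequal between the groups, so it was fitted as a covariate, which gave 10 genes. They were Brwd1 (adjusted p = 0.0252), Trappc5 (0.0320) and Bcl10 (0.0492), and Ier2, Ier5, Myc, Marcksl1, Cebpb, Vamp1 and A430078G23Rik, which were seen before being named. Within libraries of the same sex the log2 ratio of deleted to control was -0.60 and -0.54 for Brwd1, 0.75 and 0.46 for Trappc5 and 0.50 and 0.37 for Bcl10, in libraries with Xist (1 against 2) and with Y-linked counts (2 against 1).

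The 3 comparisons between germinal centre fractions ask how light zone, CXCR4+ CD83+ and CXCR4+ CD83- cells differ when all are labelled as Brwd1 deleted. Without control germinal centre libraries, the counts do not show how far Brwd1 was deleted in them. The sort markers followed the gates, with Cxcr4 at 113 ± 6.86, 309.6 ± 4.001 and 400 ± 17.8 CPM and Cd83 at 1035 ± 9.55, 527 ± 3.02 and 232.6 ± 3.8 CPM in LZ, DZp and DZd (SD, n = 2 each). Brwd1 transcript rose in the same order, from 151 ± 9.37 to 204 ± 0.339 and 255.5 ± 5.885 CPM, and its relative Phip fell, from 257 ± 17.2 to 184 ± 2.39 and 142 ± 5.61 CPM. Brwd3 stood at 28.5 ± 0.380, 21.4 ± 1.73 and 17.9 ± 0.0973 CPM, and its difference between DZd and DZp missed the threshold without DZp replicate 1 (adjusted p = 0.103). With all 12 libraries in 1 fit the difference between DZd and DZp also missed the threshold for Brwd3 (0.145) and Cxcr4 (0.301).

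**Figure D2:**
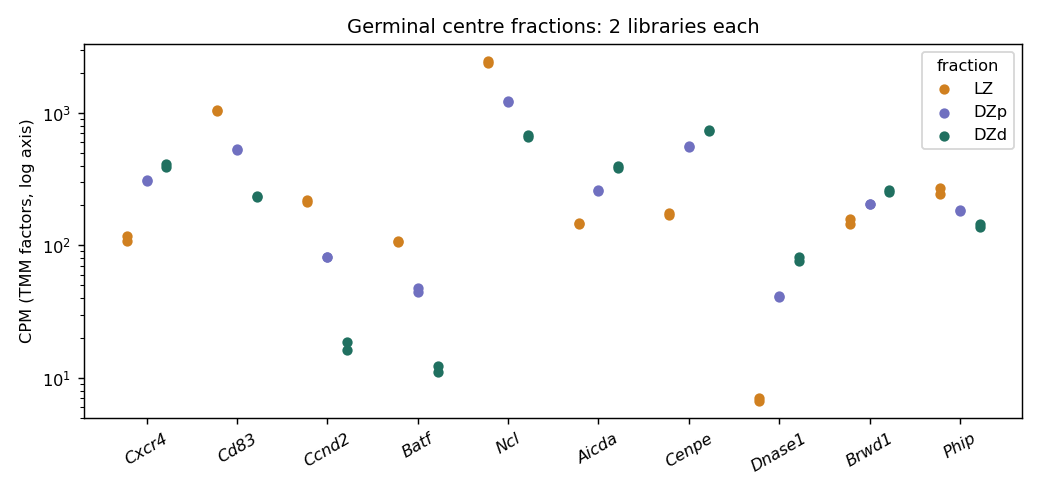
Level of 10 genes in the germinal centre fractions, in CPM with TMM factors on a log axis, with 1 point for each of the 2 libraries of a fraction. The genes were picked for display. DZp lies between LZ and DZd for each of these genes, for instance Ccnd2 at 216, 81.5 and 17.4 CPM in LZ, DZp and DZd.

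The comparison of LZ with DZp cells asks what differs between cells without and with CXCR4 when both carry CD83. Genes with the largest rise in LZ included the T cell attracting chemokine Ccl22 (18.1 ± 0.306 against 3.69 ± 0.347 CPM, log2 fold change 2.29 ± 0.13, adjusted p = 8.44e-13), the actin bundler Fscn1 (2.10 ± 0.07) and the activation receptor gene Tnfrsf8 (1.88 ± 0.08). Also among them were Nefh, Trabd2b, Plscr1, Shank1, the endocytic receptor gene Ly75, Spire1 and Ccnd2, with log2 fold changes from 1.81 for Nefh to 1.37 for Spire1. Ccnd2, the cyclin D2 that starts a new cell cycle, stood at 216 ± 5.57 and 81.5 ± 0.277 CPM. The survival genes Bcl2a1d and Bcl2a1b rose by 1.89 ± 0.11 and 1.51 ± 0.06, and reads cannot always be assigned among these near-identical paralogs. Genes with the largest fall in LZ included Dnase1 (-2.59 ± 0.06), the deubiquitinase gene Otub2 (-2.43 ± 0.04), Adhfe1 (-2.72 ± 0.07) and the chemokine-scavenging receptor gene Ccrl1 (-2.40 ± 0.07). The others among the 12 largest falls were Vcam1 (-4.05 ± 0.07, 5.32 ± 0.159 against 88.3 ± 0.0178 CPM), the iron exporter Slc40a1 (-3.76), Axl (-3.65), the mannose receptor Mrc1 (-3.65), the transferrin gene Trf (-3.06), Hmox1 (-2.83), Emr4 (-2.54) and Sdc3 (-2.38), most of them known from macrophages. Hmox1 (adjusted p = 0.0266) missed the threshold without LZ replicates 1 (0.154) or 2 (0.164), without DZp replicates 1 (0.125) or 2 (0.130) and with the replicate block (0.0526).

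The clearest list in LZ against DZp was G2/M, with 21 of 21 genes lower in LZ, a median of -1.11 and a camera adjusted p of 2.31e-13 (adjusted p = 0.262 with an estimated correlation). The kinesin gene Cenpe fell from 560 ± 6.91 to 173 ± 5.03 CPM, the mitotic kinase gene Aurka changed by -1.71 ± 0.04 and Cdc20, an activator of the anaphase-promoting complex, by -1.75 ± 0.03. Genes of DNA replication did not follow, with 15 higher, 6 lower and 1 not passing in the G1/S list (median 0.19, camera adjusted p = 0.0397, and adjusted p = 0.532 with an estimated correlation). Examples were Pcna (0.63 ± 0.04) and Mcm4 (0.58 ± 0.03). MYC targets and ribosome biogenesis genes were higher in 19 of 19 cases (median 0.81, camera adjusted p = 3.37e-10, and adjusted p = 0.330 with an estimated correlation). Members included the nucleolar genes Ncl (0.98 ± 0.03) and Npm1 (0.97 ± 0.03). Glycolysis genes were higher for 12, lower for 1 and not passing for 3, with 13 higher and 1 lower when adjusted over the list alone (median 0.44, camera adjusted p = 0.000536, and adjusted p = 0.262 with an estimated correlation). They included Ldha (0.90 ± 0.03), Hk2, which starts glycolysis (1.09 ± 0.05), and the lactate carrier Slc16a1 (1.28 ± 0.05). Oxidative phosphorylation genes were higher for 16, lower for 1 and not passing for 7 (median 0.19, camera adjusted p = 0.00586, and adjusted p = 0.262 with an estimated correlation). Heat shock genes were higher for 7 and lower for 3 (median 0.45, camera adjusted p = 0.0341, and adjusted p = 0.472 with an estimated correlation). Members included the mitochondrial chaperone Hspd1 (1.05 ± 0.04). The p53 targets were higher for 7, lower for 1 and not passing for 3, with 8 higher when adjusted over the list alone (median 0.25, camera adjusted p = 0.0421, and adjusted p = 0.472 with an estimated correlation). The p53 call was lost without DZp replicate 2 (0.0821) and with the replicate block (0.246).

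The light zone list, fixed from textbook markers and without Cd83, was higher in LZ for 19 genes, lower for 2 and not passing for 2 (median 0.62, camera adjusted p = 7.23e-07, and adjusted p = 0.262 with an estimated correlation). Examples were the costimulatory gene Cd86 (0.80 ± 0.03) and Fcer2a, which encodes CD23 (0.83 ± 0.03). NF-kB targets were higher for 12 and lower for 2 (median 0.51, camera adjusted p = 0.000536, and adjusted p = 0.472 with an estimated correlation). They included Nfkbia (0.66 ± 0.03) and Cd40 (0.65 ± 0.04). MHC class II genes were higher for 10, lower for 3 and not passing for 1 (median 0.29, camera adjusted p = 0.0337, and adjusted p = 0.605 with an estimated correlation). Ifi30, an antigen-processing reductase, changed by 0.98 ± 0.03. Dark zone and somatic hypermutation genes were lower for 9, higher for 2 and not passing for 1 (median -0.46, camera adjusted p = 0.00586, and adjusted p = 0.472 with an estimated correlation). They included Aicda, the deaminase that starts hypermutation (145 ± 2.09 against 261 ± 2.88 CPM), the repair glycosylase Neil1 (-1.48 ± 0.03) and the error-prone polymerase Polh (-1.38 ± 0.04). Germinal centre identity genes were lower for 11, higher for 3 and not passing for 1, and 12 were lower when adjusted over the list alone (median -0.29, camera adjusted p = 0.0187, and adjusted p = 0.532 with an estimated correlation). Early B lineage genes were lower for 7, higher for 1 and not passing for 2 (median -0.64, camera adjusted p = 0.00886, and adjusted p = 0.401 with an estimated correlation). The B cell factor Pax5 changed by -0.65 ± 0.03. Immediate early genes were lower for 12, higher for 2 and not passing for 6, and 13 were lower when adjusted over the list alone (median -0.20, camera adjusted p = 0.0289, and adjusted p = 0.472 with an estimated correlation). Their members moved apart, with Jun at -0.41 ± 0.03 and Egr2 at 0.62 ± 0.06, both of which missed the threshold with all 12 libraries in 1 fit (0.621 and 0.165).

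Markers of other cells differed between LZ and DZp, and most members of the myeloid and erythroid lists were lower in LZ. Myeloid markers were lower in LZ than in DZp for 13 of 14 genes, with 1 not passing (median -1.23, camera adjusted p = 8.61e-07, and adjusted p = 0.262 with an estimated correlation). Csf1r stood at 17.4 ± 0.565 CPM in LZ and 78.9 ± 0.442 CPM in DZp, and C1qb at 1.90 ± 0.323 and 22.8 ± 0.469 CPM. Erythroid markers were lower in LZ for 4 of 5 genes, and for 5 when adjusted over the list alone (median -1.61, camera adjusted p = 0.0289, and adjusted p = 0.369 with an estimated correlation). The call was lost with the replicate block (0.216). Their levels were low, with Slc4a1 at 1.13 ± 0.271, 3.23 ± 0.241 and 11.2 ± 0.406 CPM in LZ, DZp and DZd. With all 12 libraries in 1 fit Slc4a1 missed the threshold against DZp in LZ (0.352) and in DZd (0.252). T cell markers were lower in LZ than in DZp for 4 genes, higher for 1 and not passing for 5 (camera adjusted p = 0.304). Adjusted over the list alone, counts also differed for follicular and naive genes (5 instead of 4 higher), memory genes (4 instead of 3 higher), migration receptors (3 instead of 2 higher), unfolded protein response genes (7 instead of 6 higher) and NK markers (0 instead of 1 lower). The remaining lists had the same counts. The chi-square per degree of freedom of the replicate pairs was 4.56 in LZ, 3.68 in DZp and 32.51 in DZd. The DZd value includes the lens crystallin genes, with 283879 counts in DZd replicate 1 and 10 in replicate 2, so it does not measure general spread. The spread fitted for a gene was shared by all fractions. Of 13332 genes tested, 7959 passed between LZ and DZp, 4188 higher and 3771 lower in LZ, of which 170 and 795 changed by more than 2-fold. With upper-quartile factors the balance turned, with 45.2% of the genes that passed higher in LZ against 52.6% with TMM. Against a change of 1.5-fold 1116 genes passed.

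**Figure D3:**
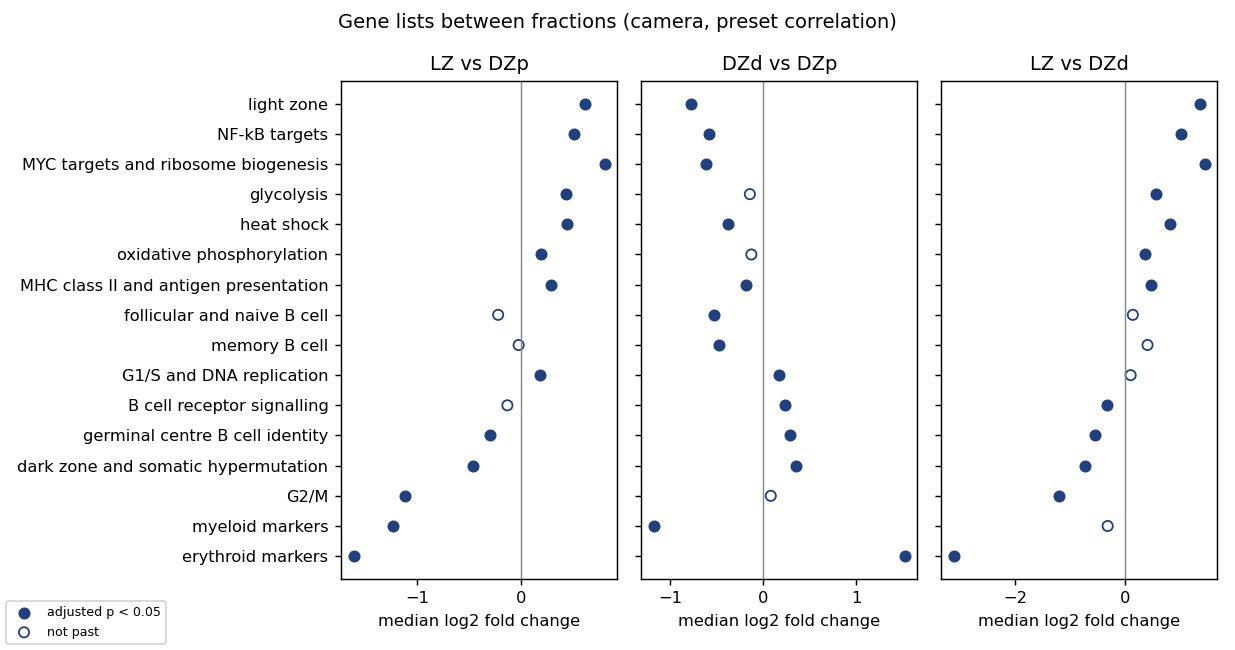
Median log2 fold change of 16 fixed gene lists in the 3 comparisons between germinal centre fractions. Filled points passed camera with its preset correlation at adjusted p 0.05 and open points did not. With an estimated correlation, a setting that also has few degrees of freedom, 0 lists passed in each comparison.

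The comparison of DZd with DZp cells asks what differs between CXCR4+ cells without and with CD83. Genes with the largest rise in DZd included the sodium channel genes Scn11a (47.7 ± 0.881 against 19.1 ± 0.0419 CPM, log2 fold change 1.32 ± 0.06, adjusted p = 9.96e-14) and Scn8a (1.08 ± 0.09), the receptor kinase gene Ret (1.20 ± 0.09), Bzrap1 (1.10 ± 0.04), the thromboxane receptor gene Tbxa2r (1.08 ± 0.08) Emp2 (1.07 ± 0.08) and the linker histone gene H1fx (1.04 ± 0.05). Scand1 (1.14 ± 0.28, adjusted p = 0.0454) missed the threshold without DZp replicates 1 (0.211) or 2 (0.194) or DZd replicate 1 (0.0585). It also missed it with no filter (0.0573), with limma-voom (0.0577), with only the 4 libraries compared (0.077) and with all 12 libraries in 1 fit (0.241). Falls in DZd included Ccnd2, from 81.5 ± 0.277 to 17.4 ± 1.68 CPM (-2.23 ± 0.05), the AP-1 family factor Batf, from 46.0 ± 2.23 to 11.7 ± 0.811 CPM (-1.97 ± 0.06), Mreg (-2.31 ± 0.09) and Ly75 (-1.82 ± 0.05). The others among the 12 largest falls were Vcam1 (-4.47 ± 0.07), Slc40a1 (-4.18), Axl (-3.89), Mrc1 (-3.54), Trf (-2.83), Emr4 (-2.08), Sdc3 (-2.06) and Emr1 (-1.93), most of them known from macrophages. Myeloid markers were lower in DZd than in DZp for 11, higher for 1 and not passing for 2 genes (median -1.18, camera adjusted p = 0.000176, and adjusted p = 0.337 with an estimated correlation). Erythroid markers were higher in DZd for 5 of 5 genes (median 1.52, camera adjusted p = 0.00519, and adjusted p = 0.337 with an estimated correlation). The call was lost with the replicate block (0.0582).

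The light zone list was lower in DZd for 21 genes, higher for 1 and not passing for 1 (median -0.78, camera adjusted p = 5.15e-09, and adjusted p = 0.337 with an estimated correlation). Its members included Irf4, a factor of B cell activation and plasma cell fate (-1.34 ± 0.03), and Myc (176 ± 2.42 against 85.0 ± 2.37 CPM in DZd, -1.05 ± 0.03). MYC targets and ribosome biogenesis genes were lower for 18 of 19, with 1 not passing (median -0.62, camera adjusted p = 1.28e-09, and adjusted p = 0.337 with an estimated correlation). They included Npm1 (-1.13 ± 0.03). NF-kB targets were lower for 12, higher for 1 and not passing for 1 (median -0.58, camera adjusted p = 5.49e-05, and adjusted p = 0.423 with an estimated correlation). The feedback inhibitor Tnfaip3 changed by -0.63 ± 0.03. Heat shock genes were lower for 8 and higher for 2 (median -0.38, camera adjusted p = 0.00664, and adjusted p = 0.423 with an estimated correlation). Immediate early genes were lower for 13, higher for 4 and not passing for 3 (median -0.22, camera adjusted p = 0.0452, and adjusted p = 0.510 with an estimated correlation). The receptor-induced factor Egr2 changed by -1.55 ± 0.06. MHC class II genes were lower for 9, higher for 2 and not passing for 3 (median -0.19, camera adjusted p = 0.0471, and adjusted p = 0.580 with an estimated correlation). H2-Aa changed by -0.59 ± 0.03, and the call was lost with the size factors of DESeq2 (0.0524). Memory B cell genes were lower for 10, higher for 1 and not passing for 1 (median -0.47, camera adjusted p = 0.00345, and adjusted p = 0.337 with an estimated correlation). They included Cd38 (-1.15 ± 0.05), Bcl2 (-0.97 ± 0.06) and the chemokine receptor gene Ccr6 (-1.17 ± 0.08).

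Follicular and naive genes were lower in DZd for 11 and higher for 3 (median -0.53, camera adjusted p = 0.000730, and adjusted p = 0.423 with an estimated correlation). The homing receptor gene Sell changed by -0.75 ± 0.05. Marginal zone genes were lower for 10 and higher for 1 (median -0.33, camera adjusted p = 0.00399, and adjusted p = 0.337 with an estimated correlation). Members included the inhibitory receptor Fcrl5 (-1.27 ± 0.07). Plasma cell genes were lower for 7, higher for 3 and not passing for 4, and 8 were lower when adjusted over the list alone (median -0.30, camera adjusted p = 0.0452, and adjusted p = 0.423 with an estimated correlation). The plasma cell regulator Prdm1 changed by -1.46 ± 0.11. Dark zone and somatic hypermutation genes were higher in DZd for 10, lower for 1 and not passing for 1 (median 0.35, camera adjusted p = 0.000375, and adjusted p = 0.423 with an estimated correlation). Members included Neil1 (0.69 ± 0.03) and the mismatch repair gene Msh6 (0.41 ± 0.03). Aicda, at 393 ± 10.8 against 261 ± 2.88 CPM, missed the threshold with all 12 libraries in 1 fit (adjusted p = 0.0886). B cell receptor signalling genes were higher for 15, lower for 2 and not passing for 1 (median 0.23, camera adjusted p = 0.000574, and adjusted p = 0.511 with an estimated correlation). The kinase Syk changed by 0.49 ± 0.03 and the coreceptor Cd19 by 0.36 ± 0.03. Germinal centre identity genes were higher for 11, lower for 3 and not passing for 1 (median 0.29, camera adjusted p = 0.00385, and adjusted p = 0.510 with an estimated correlation). G1/S genes were higher for 13, lower for 3 and not passing for 6 (median 0.17, camera adjusted p = 0.0196, and adjusted p = 0.511 with an estimated correlation). G2/M genes were higher for 10, lower for 2 and not passing for 9, and as a list did not pass (median 0.08, camera adjusted p = 0.158). Adjusted over the list alone, counts also differed for glycolysis genes (10 instead of 8 lower), migration receptors (7 instead of 6 lower), cohesin and CTCF genes (5 instead of 4 higher) and Polycomb genes (7 instead of 6 higher). The remaining lists had the same counts. Of 13332 genes tested 7139 passed, 3380 higher and 3759 lower in DZd, of which 172 and 414 changed by more than 2-fold. With upper-quartile factors 50.3% of the genes that passed were higher in DZd, against 47.3% with TMM. Against a change of 1.5-fold 524 passed, and with all 12 libraries in 1 fit 4720 passed.

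Between the outer fractions, LZ and DZd, the log2 fold change of a gene is close to the sum of both steps. The light zone, NF-kB and MYC target lists, which moved the same way in both, thus had larger medians than in either single step. Members such as Nfkbia, Nfkb2 and Cd40 are in both the light zone and NF-kB lists, so these are not separate results. Genes highest in LZ relative to DZd were Plscr1, a phospholipid scramblase (40.7 ± 0.906 against 1.99 ± 0.143 CPM, log2 fold change 4.35 ± 0.10, adjusted p = 1.29e-20), Timd2 (4.02 ± 0.08), Ccnd2 (3.63 ± 0.05) and Mreg (3.39). They were followed by Shank1 (3.37), Ly75 (3.26), Fscn1 (3.24), Batf (3.18), Trabd2b (3.17), St8sia6 (3.11), Gcsh (3.01) and Il4i1 (2.86). Genes highest in DZd were Scn8a (29.8 ± 1.40 against 2.22 ± 0.528 CPM, -3.74 ± 0.11), Dnase1 (79.4 ± 3.71 against 6.84 ± 0.258 CPM, -3.54 ± 0.06) and Adhfe1 (-3.50). After them came Ccrl1 (-3.18), Otub2 (-3.14), the Wnt pathway receptor Lgr5 (-3.09), Rgcc (-2.94), H1fx (-2.88), Reln (-2.87), Bzrap1 (-2.67), Pafah1b3 (-2.64) and Cdkn3 (-2.61). MYC targets and ribosome biogenesis genes were higher in LZ for 19 of 19 (median 1.47, camera adjusted p = 4.38e-09, and adjusted p = 0.330 with an estimated correlation). Npm1 changed by 2.10 ± 0.03. G2/M genes were lower in LZ for 20 of 21, with 1 not passing (median -1.20, camera adjusted p = 4.38e-09, and adjusted p = 0.330 with an estimated correlation). Cenpe stood at 173 ± 5.03 and 736 ± 11.1 CPM. Light zone genes were higher for 22 and lower for 1 (median 1.38, camera adjusted p = 1.51e-08, and adjusted p = 0.330 with an estimated correlation). NF-kB targets were higher for 12, lower for 1 and not passing for 1 (median 1.03, camera adjusted p = 0.000148, and adjusted p = 0.522 with an estimated correlation).

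Dark zone and somatic hypermutation genes were lower in LZ than in DZd for 10, higher for 1 and not passing for 1 (median -0.73, camera adjusted p = 0.00214, and adjusted p = 0.522 with an estimated correlation). Aicda changed by -1.43 ± 0.03. Glycolysis genes were higher in LZ for 13, lower for 2 and not passing for 1 (median 0.57, camera adjusted p = 0.00611, and adjusted p = 0.330 with an estimated correlation). Germinal centre identity genes were lower for 12 and higher for 3 (median -0.54, camera adjusted p = 0.0134, and adjusted p = 0.609 with an estimated correlation). Receptor signalling genes were lower for 15 and higher for 3 (median -0.32, camera adjusted p = 0.0135, and adjusted p = 0.686 with an estimated correlation). Syk changed by -0.81 ± 0.03 and the kinase gene Prkcb, the other way, by 0.93 ± 0.03. Immunoglobulin constant regions were lower for 7 and higher for 1 (median -0.49, camera adjusted p = 0.0135, and adjusted p = 0.522 with an estimated correlation). MHC class II genes were higher for 11 and lower for 3 (median 0.48, camera adjusted p = 0.0269, and adjusted p = 0.686 with an estimated correlation). H2-Aa changed by 1.02 ± 0.03 and the peptide-exchange subunit H2-DMb1 by -0.71 ± 0.03. Heat shock genes were higher for 7, lower for 2 and not passing for 1 (median 0.83, camera adjusted p = 0.0283, and adjusted p = 0.522 with an estimated correlation). Oxidative phosphorylation genes were higher for 16, lower for 3 and not passing for 5 (median 0.37, camera adjusted p = 0.0234, and adjusted p = 0.330 with an estimated correlation). The call was lost without DZd replicate 1 (0.0625) and with the replicate block (0.0606). Early B lineage genes were lower for 7, higher for 1 and not passing for 2 (median -0.60, camera adjusted p = 0.0392, and adjusted p = 0.522 with an estimated correlation). The call was lost without LZ replicate 2 (0.0589), DZd replicate 1 (0.0574) or DZd replicate 2 (0.0513). Erythroid markers were lower in LZ for 5 of 5 (median -3.13, camera adjusted p = 0.0134, and adjusted p = 0.330 with an estimated correlation). The call was lost with the replicate block (0.115).

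Several lists that passed in a single step did not pass between LZ and DZd. Myeloid markers had a median of -0.31 (camera adjusted p = 0.608), follicular and naive genes 0.15 (0.115), G1/S genes 0.11 (0.738), marginal zone genes 0.12 (0.535), plasma cell genes 0.09 (0.618), memory genes 0.42 (0.0543) and p53 targets 0.31 (0.1). Immediate early genes had a median of -0.06 and a mean of 0.22 (0.889). Of 13332 genes tested 9513 passed between LZ and DZd, 4876 higher and 4637 lower in LZ, of which 1103 and 1184 changed by more than 2-fold. With upper-quartile factors 46.3% of the genes that passed were higher in LZ, against 51.3% with TMM. Against a change of 1.5-fold 3468 passed, and counts adjusted over the list alone were the same as over all genes for the lists given. The DZp level lay between those of LZ and DZd for 8214 of the 9513 genes (86.3%). These genes were chosen because LZ and DZd differed, which by itself favours a DZp level between them. The share that this choice alone would give was not computed. In both steps 2634 genes passed with LZ above DZp above DZd, where independent steps would give 1181, and 2228 passed in the opposite order, where they would give 956. DZp was lowest past the threshold in both steps for 191 genes and highest for 506. Both steps share the DZp libraries, which with no true change would give them a correlation across genes of -0.54, against 0.07 measured. The covariance was -0.077 without change and 0.038 measured. Many genes did change here, so a simulation without change cannot tell whether DZp lies between the other fractions.

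Transcripts of the eye were found in the germinal centre libraries. The 10 lens crystallin genes summed to 283879 counts in DZd replicate 1 (0.701% of that library), to 241 in DZp replicate 2, 28 in DZp replicate 1, 10 in DZd replicate 2, 8 and 9 in LZ and 1 to 4 in follicular libraries. The 8 photoreceptor genes, such as the rod pigment gene Rho, summed to 205 and 204 counts in LZ, 227 and 403 in DZp and 1510 and 10 in DZd. They were picked from 12 retina genes for having almost no counts in follicular libraries, so their sum of 0 or 1 there was set by that choice. Of the retina genes left out, Rom1 had 92 to 138 counts in follicular libraries. Without DZd replicate 1, 6782 genes passed between DZd and DZp and 9222 between LZ and DZd.

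**Figure D4:**
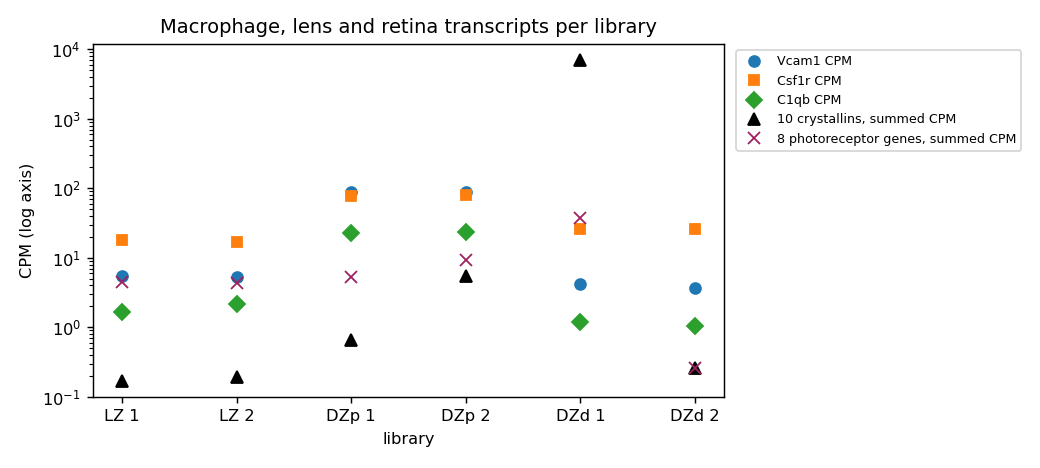
Level of macrophage genes (Vcam1, Csf1r, C1qb), of 10 summed lens crystallins and of 8 summed photoreceptor genes in each germinal centre library, in CPM on a log axis. The macrophage genes stood highest in both DZp libraries, and the crystallins in DZd replicate 1 at 7010.4 CPM.

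Germinal centre and deleted follicular B cells were compared as cell types, in libraries that also differed in Cre driver, immunization and depth. Genes of the germinal centre programme were higher by large factors in germinal centre cells, led by Nuggc, a nuclear GTPase (735 ± 377 CPM, n = 6, against 1.06 ± 0.293 CPM, n = 3, log2 fold change 9.23 ± 0.10, adjusted p = 2.79e-15). Next came S1pr2, which confines cells to the follicle (8.84 ± 0.15), Gcsam (8.77 ± 0.13) and Aicda (260 ± 108 against 0.564 ± 0.451 CPM, 8.68 ± 0.27). The spread in germinal centre cells includes the differences between fractions. Also among the 12 largest rises were the mitotic genes Bub1 (7.54), Espl1 (7.52), Kif2c (7.48) and Gpsm2 (7.27), the transcription factor genes Mef2b (7.28) and Trerf1 (7.29), and Lrrc32 (7.51) and BC030867 (7.35). Of 8 immunoglobulin constant region genes 6 were higher, 1 was lower and 1 did not pass, and the list did not pass (median 4.81, camera adjusted p = 0.0775). The switched Ighg1 stood at 1550 ± 356 and 1.15 ± 0.110 CPM, while Ighd fell to 259 ± 35.0 from 2214 ± 151 CPM. Brwd1 stood lower in germinal centre cells, at 199 ± 45.9 against 302 ± 15.2 CPM (-0.64 ± 0.04), as did Phip (-1.11 ± 0.04) and Brwd3 (-1.01 ± 0.07).

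The 12 largest falls in germinal centre cells were all ribosomal protein genes, from Rpsa (8.54 ± 0.848 against 2409 ± 230 CPM, -8.14 ± 0.07) through Rpl21 (-7.86), Rpl11 (-7.82), Rps28 (-7.55), Rps29 (-7.53), Rpl23a (-7.50), Rpl24 (-7.47), Rpl19 (-7.32), Rpl9 (-7.16), Rps23 (-7.11) and Rps17 (-7.05) to Rpl13 (-6.91). Of 81 ribosomal protein genes tested 76 were lower and 4 higher, with a median of -3.63. The median fold change went down with the share of a gene's words found in processed pseudogenes, among other genes from 0.13 under 2% to -1.51 at 50% or more. Among ribosomal protein genes it went from -0.45 at 2 to 10% (6 genes) to -3.91 at 50% or more (36 genes). Single members of the metabolic lists fell too, with the respiratory genes Cox7c at -4.45 ± 0.06 and Cycs at -4.92 ± 0.08 and the glycolytic genes Pgk1 at -3.42 ± 0.09 and Gapdh at -1.79 ± 0.06. As lists they did not pass. Oxidative phosphorylation had 13 higher, 7 lower and 4 not passing (median 0.11, camera adjusted p = 0.901). Glycolysis had 9 higher, 6 lower and 1 not passing (median 0.33, 0.789). Whether members with pseudogene words fell more within these lists was not tested. Genes with under 10% shared words, ranked after the values had been seen, gave as largest falls Rnf144a (-3.85), the homing receptor gene Sell (73.3 ± 18.6 against 1020 ± 101 CPM, -3.83 ± 0.06), the chemokine receptor genes Ccr6 (-3.82) and Ccr7 (-3.50), Gpr174 (-3.65) and Irf2bpl (-3.59).

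**Figure D5:**
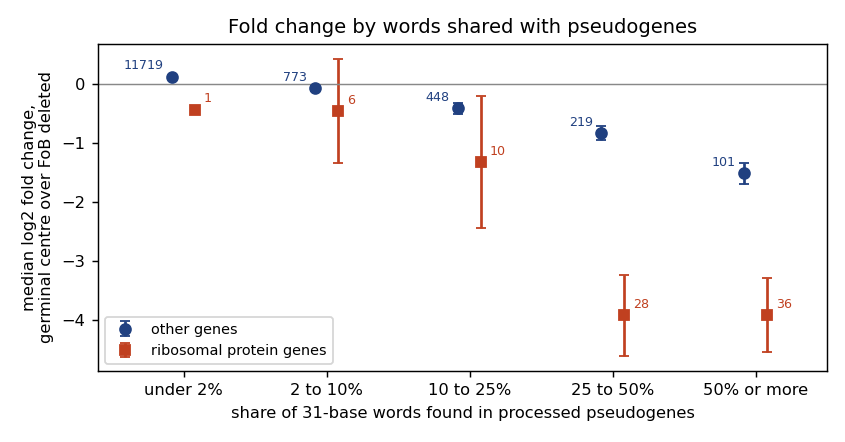
Median log2 fold change of germinal centre over deleted follicular cells, for genes grouped by the share of their 31-base words that occur in processed pseudogenes. Bars are bootstrap standard errors and printed numbers are genes per group. The medians of other genes go from 0.13 to -1.51 and those of ribosomal protein genes from -0.43 to -3.91.

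Cell cycle and germinal centre lists were higher in germinal centre cells. G2/M genes were higher for 21 of 21 (median 5.70, camera adjusted p = 5.63e-13, and adjusted p = 0.316 with an estimated correlation). Cenpe stood at 478 ± 251 and 6.64 ± 0.0655 CPM. G1/S genes were higher for 21 of 22, with 1 not passing (median 3.20, camera adjusted p = 2e-11, and adjusted p = 0.209 with an estimated correlation). The replication licensing gene Cdc6 changed by 6.22 ± 0.09. Germinal centre identity genes were higher for 13 and lower for 1 (median 6.03, camera adjusted p = 9.67e-08, and adjusted p = 0.209 with an estimated correlation). Dark zone and somatic hypermutation genes were higher for 11 and lower for 2 (median 2.25, camera adjusted p = 0.000234, and adjusted p = 0.209 with an estimated correlation). Follicular and naive genes were lower for 11 and higher for 1 (median -2.74, camera adjusted p = 2.46e-05, and adjusted p = 0.187 with an estimated correlation). Bcl2 stood at 31.1 ± 8.92 against 241 ± 12.1 CPM. Migration receptors were lower for 10 and higher for 2 (median -2.40, camera adjusted p = 0.00316, and adjusted p = 0.209 with an estimated correlation). The gut homing integrin gene Itgb7 changed by -3.03 ± 0.04. Interferon response genes were lower for 15 and higher for 1 (median -1.37, camera adjusted p = 0.000460, and adjusted p = 0.584 with an estimated correlation). Stat1 changed by -0.92 ± 0.03. MHC class II genes were lower for 11 and higher for 3 (median -0.81, camera adjusted p = 0.0465, and adjusted p = 0.618 with an estimated correlation). H2-Aa stood at 1478 ± 452 and 4602 ± 400 CPM, and the call was lost without deleted follicular replicate 2 (0.0504) or DZd replicate 1 (0.0583). Myeloid markers were higher for 8, lower for 2 and not passing for 4 (camera adjusted p = 0.0679). Counts adjusted over the list alone were the same as over all genes. Of 13496 genes tested 11061 passed, 5630 higher and 5431 lower, of which 2976 and 2421 changed by more than 2-fold. Against a change of 1.5-fold 6834 passed, and 11215 passed against the control follicular libraries instead of the deleted ones.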

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

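The sex covariate, the removal of Rn45s and the removal of genes with shared words were chosen after the data had been seen. For deleted against control follicular cells, 3 genes also passed with either other scaling, without immunoglobulin genes, with a mean count of at least 50 and without Rn45s. There were 23 without a filter on low counts, 64 with DESeq2, 2 with limma-voom, 11 with sample quality weights, 0 with glmTreat against 1.5-fold (where edgeR without a minimum fold gave 1045 genes at an unadjusted p under 0.05), 1 at a threshold of 0.01, 69 with all 12 libraries in 1 fit and 10 with sex as a covariate. Leaving out 1 library gave 0 to 34 genes. The cause was not tested, except that a threshold or a minimum fold is stricter by construction. With the replicate block 5 genes passed (Brwd1, Trappc5, Myc, Dusp2 and Vamp1), while same-number libraries correlated at 0.43, -0.25 and 0.24. Libraries of the same sex correlated positively and those of opposite sex negatively, whatever their number. The correlations therefore cannot tell whether the numbers pair the libraries. Against 11 lists called, counted over all lists tested, 0 passed with an estimated correlation, 2 with fry, 9 with sex as a covariate and 5 to 14 without 1 library, the lowest without deleted replicate 3, and 13 with the replicate block. The 2 lists that passed with fry were the light zone (adjusted p = 0.0359) and migration receptor (0.0443) lists. The G2/M list pointed the other way without control replicate 2 (adjusted p = 0.731), ran from 0.000105 without control replicate 3 to 0.805 without deleted replicate 2, and the cause was not tested.

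Between fractions, glmTreat left 1116 genes for LZ against DZp, 524 for DZd against DZp and 3468 for LZ against DZd. All 12 libraries in 1 fit gave 4720 genes for DZd against DZp, and the cause was not tested. The replicate block gave 7895, 7058 and 9441 genes and 18, 18 and 15 lists, while same-number libraries correlated at -0.096, 0.021 and 0.011. Leaving out 1 library leaves its fraction with 1 library, which is then assumed to vary like the others. The DZd pair had the largest chi-square per degree of freedom (32.51), which includes the lens transcripts of replicate 1. With an estimated correlation 0, 0 and 0 lists passed, and with fry 26, 28 and 25. For germinal centre against follicular cells, glmTreat left 6834 genes, a fit with only 2 groups 9049, and removal of genes with shared words 9271. Leaving out 1 library gave 10534 to 11162 genes and 7 to 11 lists. With an estimated correlation 0 lists passed and with fry 26. No paired analysis was possible because the follicular and germinal centre libraries came from different mice. Depth, from 19.4 to 47.1 M counts, and 2 or 3 libraries per group limit the smallest changes, of which simulated 1.3-fold ones were found for 17 of 50 genes in follicular cells.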

Other observations

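The test of processed pseudogenes was chosen after its result had been seen, and the other tests before theirs.

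Chromatin regulators changed between germinal centre fractions in gene-specific directions. Smarca4, the ATPase of a chromatin remodelling complex, rose from 459 ± 8.81 CPM in LZ to 980 ± 7.54 in DZp and 1527 ± 49.8 in DZd (SD, n = 2 each), while the Polycomb gene Suz12 (287 ± 2.73, 195 ± 3.12 and 147 ± 6.79 CPM) and the demethylase gene Kdm6b (103 ± 1.51, 70.2 ± 3.55 and 38.6 ± 1.71 CPM) fell in that order. Between LZ and DZd the Polycomb and chromatin remodelling list had 7 genes higher, 9 lower and 1 not passing, and as a list it did not pass (camera adjusted p = 0.991). The cohesin and CTCF list did not pass either, with 6 higher, 3 lower and 2 not passing (0.738), among them the cohesin loader Mau2 (-0.77 ± 0.03) and the regulator Pds5a (0.57 ± 0.04). In follicular cells neither list differed between deleted and control libraries, with camera adjusted p of 0.260 and 0.644.

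Single genes of protein folding and survival differed between LZ and DZd, while their lists did not pass. Between LZ and DZd the unfolded protein response list had 8 genes higher and 7 lower (camera adjusted p = 0.354), with the chaperone Calr at 691 ± 3.51 and 344 ± 2.56 CPM in LZ and DZd and Asns, which makes asparagine, with a log2 fold change of 1.75 ± 0.06. The BCL2 family had 8 higher, 4 lower and 1 not passing (0.150), with the survival gene Bcl2l1 at 52.1 ± 1.57 CPM in LZ and 15.4 ± 1.07 CPM in DZd. NK and cytotoxic markers had 2 higher, 1 lower and 6 not passing, with 1 higher and 0 lower when adjusted over the list alone (0.991), with the T-box factor Tbx21 at 43.0 ± 0.320 and 24.6 ± 0.392 CPM. Dendritic cell markers had 3 higher, 2 lower and 1 not passing (0.738), with the receptor kinase Flt3 at 50.8 ± 1.96 and 73.8 ± 1.96 CPM. The sex-linked list had 4 higher and 1 not passing (0.0501), and 5 higher when adjusted over the list alone.

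Lens transcripts were abundant in 1 library, DZd replicate 1, and traces were found in DZp replicate 2. RNA or reads of eye in this library are a candidate explanation, since 10 of 13 further lens genes and 9 of 12 retina genes had at least 20 counts and over 10 times their CPM in DZd replicate 2. Photoreceptor genes were lower in that second library (10 counts) than in LZ and DZp (204 to 403), so part of the retina contrast rests on it. No biological explanation was tested, and the B220, GL7 and CD95 gates are meant to leave eye cells out. Whether the transcripts entered at dissection, library preparation or sequencing stays open.

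Macrophage transcripts were higher in both DZp libraries than in LZ or DZd. A sort of DZp with more of every other cell type alike is unlikely, since the T cell list, which did not pass, had a median log2 fold change of DZp over DZd of 0.24 (bootstrap SE 0.09) and over LZ of 0.44, against 1.45 (SE 0.36) and 2.16 for 18 macrophage genes listed before their values were seen, and 1.22 and 2.16 without Hmox1 and Emr1, which were later among the 12 largest falls. The neutrophil list had medians of 0.76 over DZd and 1.03 over LZ, so more myeloid cells of several kinds stay open. RNA of splenic macrophages may account for the signal but was not settled, and expression by the DZp cells themselves was not tested. The B220, GL7 and CD95 gates are meant to leave macrophages out, but the purity of the sort was not measured here. Of the 18 macrophage genes 66.7% were higher in DZp than in both other fractions past the threshold (68.8% of 16 without Hmox1 and Emr1), while the abundant Apoe (489, 799 and 1170 CPM in LZ, DZp and DZd) and Lyz2 (126, 166 and 192 CPM) were highest in DZd.

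Ribosomal protein transcripts stood far lower in germinal centre than in follicular libraries. Short transcripts are unlikely to explain this, since other genes under 1000 bases with few shared words had a median log2 fold change of 0.06. Reads that match processed pseudogenes may have been dropped in the germinal centre libraries only, since other genes with at least 50% of words in such pseudogenes lay at -1.63 relative to those under 2%. For reads shared with any annotated gene the median was -0.61 over 584 genes, between the bounds set in advance, so this wider explanation stays open. A change of ribosomal protein transcription cannot be told apart, because genes with few shared words lay 3.16 (SE 1.05) above those with many, close to the bound of 3, and there were 6 of them.

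Other splits of the libraries were counted. For deleted against control follicular cells, the 10 splits of 6 libraries are too few for a share under 0.05. The real split gave 3 genes, 2 of the 10 splits gave at least as many, and the highest other value, 9 genes, came from the split by sex. With sex as a covariate the comparison of genotypes gave 10 genes. For germinal centre against follicular cells fitted as 2 groups, 1 of 84 splits, the real one, gave at least 9049 genes, and the highest other value was 2. Each other split had germinal centre libraries in both groups, so the difference between cell types became spread within groups. Low counts were therefore set in advance, and the splits cannot test chance for that count.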
